A study of Mus musculus with 48 samples.

How the data were processed

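RNA from liver, kidney and hypothalamus of male and female mice, from testis and from ovary was measured on Affymetrix arrays. Per the labels, purchased RNA was used, polyA-selected for liver, kidney, ovary and testis and total for hypothalamus, while another field of the labels gives total RNA for every sample. Sexes were compared within a tissue, and testis against ovary, so this difference in RNA does not run along a comparison, but it does run along the tests between hypothalamus and another tissue. Each RNA sample is described as a pool of 10 animals. The deposited values are intensity values on a linear scale, 1 per probe set and array. The software and the summary of probe sets are not given in the sources used here. The 2% trimmed mean of the deposited intensity lay between 500.11 and 500.23 on all 48 arrays, so the arrays share a common scale.

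Samples were grouped by the titles of the arrays into 8 groups with 3 RNA samples each and 2 arrays per RNA sample. The correlation between the 2 arrays of an RNA sample lay between 0.9656 and 0.9899, and 0 pairs of arrays had identical values. Of the probe sets, 64 controls were left out. Of the remaining 22626, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none, and 20351 were matched by Entrez ID to the gene table of assembly GRCm38.p6, which served for symbols and chromosomes only. Probe sets with several symbols or none are not named, and probe sets whose design is shared between related genes, as those of Xist, Ces1f and Slc22a29, may read more than their named gene.

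Arrays were scaled to a common 2% trimmed mean. Values were taken as log2 of the scaled intensity plus a pseudocount of 48.1, the 20th percentile of all scaled values, and the 2 arrays of an RNA sample were averaged. The pseudocount shrinks the differences of dim genes, so a log2 difference understates the ratio of intensities there. Detection calls were not used here. A probe set was tested where it lay above the 40th percentile of its array in at least 3 RNA samples of the comparison. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in a fit of the 6 RNA samples of the 2 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. Intensities are given as means with SD over the 3 RNA samples of a group, and log2 differences with the SE of the fit. Differences between tissues in the male-female difference were tested as interaction terms in a joint fit of the 18 RNA samples of the 6 groups of liver, kidney and hypothalamus. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

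Where a gene had several tested probe sets, the brightest stood for it. Before the data were examined, 41 lists of genes, the rule for naming genes and the comparisons were fixed. The lists covered sex-linked genes, enzymes, pathways and markers of cell types, and a list was tested where at least 3 members were measured. Shifts of lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Of the 22 lists tested in liver, 6 passed with the preset correlation and 1 with the estimated correlation. Of 23 in kidney these numbers were 9 and 0, of 16 in hypothalamus 3 and 1, and of 13 in testis against ovary 7 and 0. The 16 liver, 14 kidney, 13 hypothalamus and 6 gonad lists that did not pass had a lowest adjusted p of 0.117, 0.229, 0.115 and 0.121.

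The rule for naming genes took the 10 genes with the largest positive and the 10 with the largest negative difference among those that passed and whose 3 values in a group lay all above those of the other, up to 4 members with the lowest p of each list described, and a set of sex-linked genes. For the interactions it took the 5 genes with the largest difference in each direction. Genes on the X chromosome were compared with autosomal genes by Fisher's exact test. Tested on simulated data with the means and fitted spreads of the real probe sets, the fit called 80% of 2-fold changes in liver, 72% in kidney, 100% in hypothalamus and 90% in testis against ovary, with 50 changed probe sets of each size among 13794, 13806, 13771 and 14928. Of 1.5-fold changes it called 2%, 4%, 82% and 12%. The simulated noise was independent and normal, with the fitted spreads taken as the true ones and no link between samples of the same number. These shares therefore do not give the power in the real samples. In kidney Slco1a1 differed 17.2-fold and did not pass (limma adjusted p = 0.116), so an uncalled gene may differ by more than 2-fold.

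Samples of the same number in both sexes deviated together. The correlation of their deviations from the group means was 0.536, 0.139 and 0.482 for numbers 1, 2 and 3 in liver, 0.591, 0.426 and 0.627 in kidney, and 0.39, 0.101 and 0.328 in hypothalamus, all above 0.1, and 0.0419, 0.146 and 0.0426 in the gonads. The highest correlation between samples of different numbers was 0.287 in liver, -0.118 in kidney, 0.0895 in hypothalamus and 0.0327 in the gonads. Closest to the sample of their own number were 5 of 6 liver samples and all 6 each of kidney, hypothalamus and gonads. The numbers were therefore taken to pair the samples of liver, kidney and hypothalamus, least clearly for number 2 in liver and hypothalamus, from the data alone, since the labels do not say what a number stands for. The gonads were not taken as paired, with numbers 1 and 3 under the limit of 0.1, though their samples were also closest to their own number. The fit without the block was chosen before that, and the counts of probe sets with the replicate number as a block are given beside it. For named genes and gene lists the results with the block are given in part.

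Alternatives were quantile normalization, median centring, no further scaling, 0.25 and 4 times the pseudocount, no filter, a filter at the 60th percentile, each array of a sample alone, all arrays with the RNA sample as a random block, all 8 groups in 1 fit, an intensity trend with robust variances, the replicate number as a block, and leaving out each RNA sample. The filter was applied again after a sample was left out, so a probe set expressed in 1 group alone was then untested without any 1 sample of that group. Leaving out each sample with the probe sets of the full comparison kept, the block for gene lists and part of the alternatives for the X-linkage odds ratios were added after seeing the data.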

Results

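RNA from male and female mice was measured on 48 arrays, in 8 groups: male and female liver, male and female kidney, male and female hypothalamus, testis and ovary. Each group held 3 RNA samples, and each RNA sample was hybridised to 2 arrays, so n = 3 per group throughout. Every array had a trimmed mean intensity between 500.11 and 500.23, and array medians lay between 163.3 and 276. The number of arrays limits the precision of these values. Per the labels, each RNA sample was a pool of 10 animals. The labels do not say that the 3 samples of a group came from separate pools, so p-values measure a spread between samples that may be technical. For each gene said to rise or fall in its own right, all 3 values of 1 group lay above all 3 of the other, which chance gives for 10% of genes.

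The comparison of male and female liver, kidney and hypothalamus asks which transcripts differ between the sexes, the subject named in the title of the series. Xist, the non-coding RNA that coats the inactive X chromosome, had a mean intensity of 794 ± 122 (SD, n = 3) in female and 262 ± 39.4 in male liver, and of 1660 ± 245 in female and 249 ± 18.7 in male hypothalamus. Eif2s3y, a Y-linked gene for a translation initiation factor subunit, had 275 ± 63.1 in male and 4.82 ± 1.18 in female liver, and 170 ± 48.1 in male and 3.48 ± 2.84 in female kidney. Uty, a Y-linked relative of a histone demethylase, had 197 ± 46.0 in male and 31.7 ± 6.22 in female kidney. In hypothalamus, Kdm5d, a Y-linked histone demethylase, differed by 1.62 ± 0.19 (log2, SE, adjusted p = 0.0236) and Uty by 1.33 ± 0.12 (adjusted p = 0.00371). In female kidney, Xist had 511 ± 260 against 187 ± 41.4 in male kidney, and the log2 difference of -1.18 ± 0.30 did not pass the test (adjusted p = 0.472). The sex difference in Xist was not shown to differ between liver and kidney (log2 -0.26 ± 0.33, adjusted p = 0.9998). All Xist values here are of its brightest probe set, of a shared design, which read 151.1 to 285.4 in male samples of these tissues. Other probe sets of Xist, if tested, are not given, so a call missed or lost here does not speak for them. A list of X-linked genes known to escape inactivation, with Xist added to them, had 7 measured members. All 7 were lower in male liver by sign, and the list fell with an adjusted p of 2.76e-10 by camera, but with adjusted p = 0.127 with an estimated correlation. In that list 1 gene, Xist, passed over all genes, and 2 passed adjusted over the list alone. The same list in hypothalamus fell with adjusted p = 1.89e-10, and with adjusted p = 0.0457 with an estimated correlation, with 1 of 7 genes called and 4 adjusted over the list alone. In kidney it fell with adjusted p = 0.000798, and with adjusted p = 0.277 with an estimated correlation, with 0 of 8 genes called by limma (3 at an unadjusted p under 0.05) and 1 adjusted over the list alone. The Y-linked list rose with adjusted p = 4.4e-13 in liver (adjusted p = 0.105 with an estimated correlation) and with adjusted p = 8.77e-11 in hypothalamus (adjusted p = 0.0637 with an estimated correlation). In liver 1 of 4 Y-linked genes was called and 3 were adjusted over the list alone, and in hypothalamus 2 of 3 were called and 2 adjusted over the list alone. The call of Xist in liver was lost without any 1 of the 6 liver samples (adjusted p from 0.163 to 0.363), the call of Uty in kidney without female kidney 1 or 2 (0.0606 and 0.0779), and that of Kdm5d in hypothalamus without female hypothalamus 3 (0.125). With the probe sets of the full comparison kept, Kdm5d was also lost without male hypothalamus 1, 2 or 3 (0.135, 0.133 and 0.0573). With first arrays only, Xist in liver (0.0722) and Kdm5d and Uty in hypothalamus (0.433 and 0.187) did not pass, and Xist in liver also did not with median centring (0.0526), 4 times the pseudocount (0.0526), no filter (0.102) or all 8 groups in 1 fit (0.0708), Kdm5d in hypothalamus with 0.25 times the pseudocount (0.11) or no filter (0.176), and Uty in kidney with 4 times the pseudocount (0.0512).

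**Figure D1:**
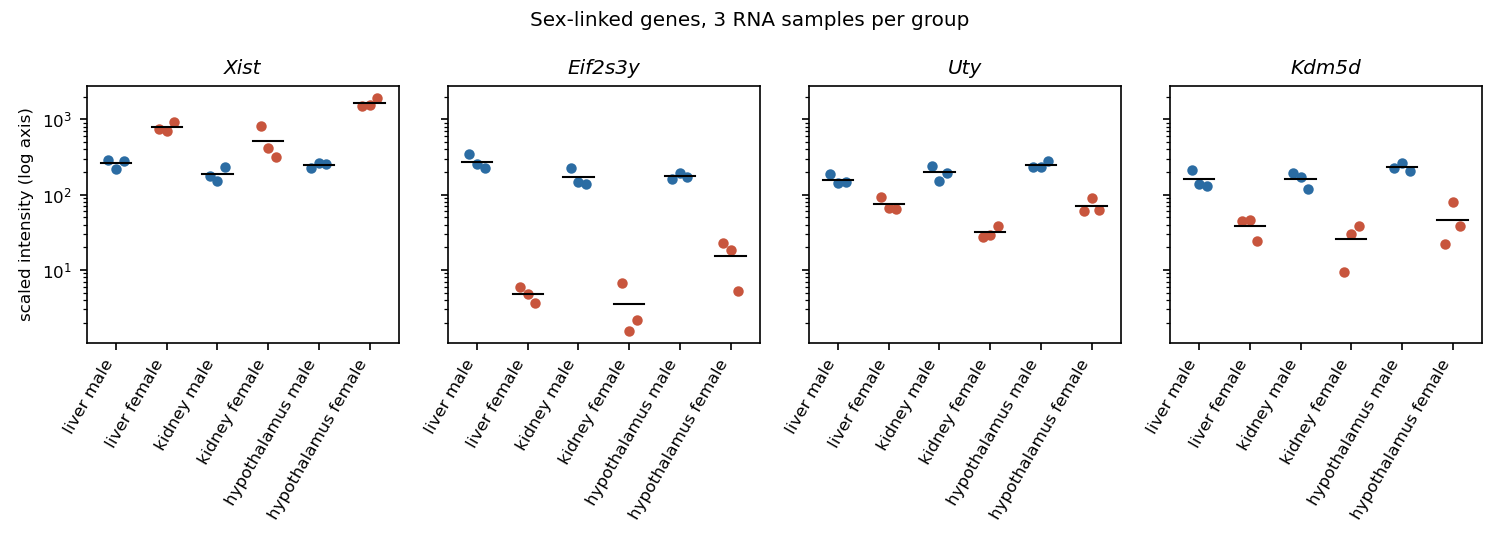
Scaled intensity (log axis) of Xist and of 3 Y-linked genes in each RNA sample of liver, kidney and hypothalamus, with blue points for male samples, red points for female samples and black bars for group means. Eif2s3y lies between 138 and 347 in the male samples and between 1.55 and 22.9 in the female samples, and Xist in female kidney lies between 312 and 805.

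In male liver, Cyp4a12a, a fatty acid hydroxylase of the cytochrome P450 family, rose to 2550.8 ± 1246.5 (SD, n = 3) from 121 ± 49.0 in female liver, a log2 difference of 3.87 ± 0.39 (SE, adjusted p = 0.027). Genes known from the literature as male-predominant in liver were higher in male liver in 21 of 22 measured cases. Hsd3b5, a steroid-reducing enzyme, had 715 ± 490 in male and 8.45 ± 2.98 in female liver (log2 difference 3.45, adjusted p = 0.251). Elovl3, a fatty acid elongase, had 570 ± 210 in male and 172 ± 29.8 in female liver (adjusted p = 0.515). Genes known as female-predominant were lower in male liver in 25 of 31 cases, among them Cyp3a16, a cytochrome P450 with 22.7 ± 18.6 in male and 378 ± 206 in female liver (adjusted p = 0.239), and Cyp2b13, another P450 with 1167 ± 369 in male and 3871 ± 1021 in female liver (adjusted p = 0.356, and 0.00656 with the replicate number as a block). The male-predominant list rose (camera adjusted p = 9.39e-25, adjusted p = 0.105 with an estimated correlation), with 1 gene called over all genes and 7 adjusted over the list alone. The female-predominant list fell (adjusted p = 1.04e-17, adjusted p = 0.0456 with an estimated correlation), with 0 genes called by limma (14 at an unadjusted p under 0.05) and 9 adjusted over the list alone. The call of Cyp4a12a was lost without any 1 liver sample other than male liver 2 (adjusted p from 0.0887 to 0.212), and with 4 times the pseudocount (0.0526), no filter (0.0955) or an intensity trend (0.0747).

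Cholesterol synthesis genes fell together in male liver (camera adjusted p = 8.68e-07, adjusted p = 0.475 with an estimated correlation). All 19 measured members were lower in male liver by sign, with a median log2 difference of -0.28. Sqle, a squalene-oxidising enzyme of the pathway, had 831 ± 406 (SD, n = 3) in male and 1478 ± 653 in female liver, and Srebf2, the transcription factor that drives the pathway, 453 ± 24.8 and 557 ± 31.6. By limma 0 of its genes were called over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Acute phase proteins, which the liver secretes in inflammation, fell with a median of -0.13 (adjusted p = 0.0484, adjusted p = 0.844 with an estimated correlation, adjusted p = 0.107 with the replicate number as a block), with 0 of 18 called by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Immune cell markers, lower in male liver by sign in 23 of 26 cases, did not pass (adjusted p = 0.117, adjusted p = 0.9 with an estimated correlation), but did under quantile normalization (0.0361) and with the block (0.00017). Exocrine pancreas markers, digestive enzymes of another organ, did not pass the test between the sexes in liver (adjusted p = 0.304), and Cpb1, a pancreatic carboxypeptidase, had 3259 ± 2112 in male and 2072 ± 1275 in female liver.

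In the liver 7 of 13794 tested probe sets passed an adjusted p of 0.05, 4 higher in male and 3 in female liver, and 270 had an unadjusted p under 0.05. With the replicate number as a block, 11 probe sets passed, 7 higher in male and 4 in female liver, with Kdm5d now among them (adjusted p = 0.0417). H2-Ab1, a chain of an MHC class II protein chosen after its values were seen, had 774.5 in male liver 1 and 1010 in female liver 1, against 3838 to 8953 in the other liver samples. Leaving out any 1 of the 6 liver samples left 1 to 3 calls. The filter was applied again there, and Eif2s3y was then untested without any 1 male liver sample. With the probe sets of the full comparison kept, 5 of the 7 calls were kept and 2 gained without male liver 2, 5 kept and 1 gained without female liver 3, and 4 kept without each of the other 4 samples.

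In male kidney, Ugt2b37, a UDP-glucuronosyltransferase that conjugates steroids and drugs, rose to 2864.5 ± 1713 (SD, n = 3) from 19.6 ± 13.3 in female kidney, a log2 difference of 5.24 ± 0.44 (SE, adjusted p = 0.00355). Acsm3, a medium-chain acyl-CoA synthetase, rose by a log2 difference of 4.84 ± 0.49 and Cyp2j13, a cytochrome P450, by 4.67 ± 0.45. Cyp7b1, an oxysterol hydroxylase, rose by 4.10 ± 0.33, Slc22a30, an organic ion transporter of its family, by 3.66 ± 0.40, and Slc7a13, an amino acid transporter, by 3.35 ± 0.19. Pzp, a protease inhibitor, rose by 3.66 ± 0.33, Ces1f, a carboxylesterase, by 3.15 ± 0.33, and Ugt8a, a galactosyltransferase, by 2.65 ± 0.18. In female kidney, Bhmt, which methylates homocysteine, had 1791 ± 165 against 181 ± 62.3 in male kidney, a log2 difference of -3.04 ± 0.20 (adjusted p = 0.00135). Serpina6, the carrier of glucocorticoids in blood, fell by 2.46 on the log2 scale in male kidney. Abcc3, an efflux pump for organic anions, fell by 1.89, and Aadat, an enzyme of kynurenine metabolism, fell by 1.65. Gsta2, a glutathione transferase, fell by 1.41, and Dio1, which activates thyroid hormone, fell by 1.30.

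Genes known from the literature as androgen-regulated in kidney were higher in male kidney in 27 of 34 measured cases, with a median log2 difference of 0.71. Over all genes 9 of them rose and 2 fell, and adjusted over the list alone 17 rose and 2 fell. The list had an adjusted p of 3.55e-26 by camera and adjusted p = 0.115 with an estimated correlation. Cytochrome P450 enzymes rose as a list (15 of 27 genes higher by sign, a median of 0.13, 4 called, all higher in male kidney, 6 higher and 1 lower adjusted over the list alone, adjusted p = 0.00222, adjusted p = 0.118 with an estimated correlation), among them Cyp2e1, an ethanol-oxidising enzyme, at 8597 ± 1376 (SD, n = 3) in male and 2592 ± 478 in female kidney (adjusted p = 0.0102). Glutathione S-transferases fell, with 13 of 18 lower by sign, 1 called and 2 adjusted over the list alone (adjusted p = 1.95e-06, adjusted p = 0.116 with an estimated correlation). The male-predominant liver list rose in kidney, with 11 of 17 genes higher by sign, a median of 0.14, 2 called and 5 adjusted over the list alone (adjusted p = 1.51e-06, adjusted p = 0.115 with an estimated correlation). The female-predominant liver list did not pass there (adjusted p = 0.254). Cyp2d9 of the male-predominant list, a cytochrome P450, rose by a log2 difference of 2.02 ± 0.21. These lists overlap. The called P450 genes were Cyp2j13, Cyp7b1, Cyp2d9 and Cyp2e1, the called glutathione S-transferase was Gsta2, and the male-predominant liver genes called were Cyp7b1 and Cyp2d9. All of them are also on the androgen-regulated list, so their calls are not separate results. With the replicate number as a block, 16 androgen-regulated genes rose and 2 fell over all genes, 6 P450 genes rose and 1 fell, 3 glutathione S-transferases fell, and 5 genes of the male-predominant liver list rose.

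All 22 markers of the loop of Henle, distal tubule and collecting duct were lower in male kidney by sign, with a median log2 difference of -0.32 (adjusted p = 6.7e-09, adjusted p = 0.0843 with an estimated correlation). Slc12a3, the thiazide-sensitive transporter of the distal tubule, had 2423 ± 193 (SD, n = 3) in male and 3278 ± 290 in female kidney. All 10 glomerular markers were lower by sign, with a median of -0.25 (adjusted p = 0.000562, adjusted p = 0.115 with an estimated correlation), as in Podxl, a surface protein of podocytes, at 1253 ± 221 and 1762 ± 137. All 14 proliferation genes were higher in male kidney by sign, with a median of 0.28 (adjusted p = 2.52e-05, adjusted p = 0.344 with an estimated correlation), as in Cdk1, the kinase of mitosis, at 223 ± 50.7 and 132 ± 36.2. All 5 exocrine pancreas markers were lower by sign (adjusted p = 0.00398, adjusted p = 0.387 with an estimated correlation), as in Cela1, an elastase, at 2424 ± 435 and 3364 ± 486. Other genes of that list were far dimmer in male and female kidney, such as Ctrb1 (116 and 228.5) and Cel (150.4 and 180.2). Cel was about as bright in male and female hypothalamus (181.9 and 184.1), but Ctrb1 had 109.5 and 65.11 there and Cela1 334 and 293.2. Whether this list reads pancreas tissue in kidney was not tested. By limma 0 genes of these 4 lists were called over all genes and 0 adjusted over the list alone, with 7, 3, 1 and 1 at an unadjusted p under 0.05. Proximal tubule markers had adjusted p = 0.972, with 0 of 21 called by limma, 1 adjusted over the list alone and 1 at an unadjusted p under 0.05, and with the replicate number as a block 3 were called higher in male kidney.

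In the kidney 32 of 13806 probe sets passed, 18 higher in male and 14 in female kidney, and 671 had an unadjusted p under 0.05. With the replicate number as a block, 144 passed, 93 higher in male and 51 in female kidney. With the filter applied again, leaving out any 1 sample gave 10 to 37 calls, of which 10 to 21 were among the 32. Ugt2b37, Acsm3, Cyp2j13, Cyp7b1, Eif2s3y and Uty were then untested without any 1 male kidney sample, and Serpina6 and Abcc3 without any 1 female kidney sample. With the probe sets of the full comparison kept, 21 of the 32 calls were kept without male kidney 1, 29 of them among 53 calls without male kidney 2, 21 without male kidney 3, 19 among 20 without female kidney 1, 15 without female kidney 2 and 23 among 25 without female kidney 3. The split of these calls was uneven, with 15 higher in male and 6 in female kidney without male kidney 1 or 3, 14 and 6 without female kidney 1, 11 and 4 without female kidney 2 and 17 and 8 without female kidney 3. With the filter applied again and without female kidney 2, the calls of Acsm3, Slc22a30, Ces1f, Aadat, Gsta2, Dio1 and Cyp2e1 were lost (adjusted p from 0.0621 to 0.183), and all of these but Acsm3 without male kidney 3 (0.0512 to 0.0977). Slc22a30, Aadat, Gsta2 and Dio1 were also lost without female kidney 1 (0.063 to 0.129), Gsta2, Dio1 and Cyp2e1 without male kidney 1 (0.0712 to 0.127), and Dio1 without male kidney 2 (0.0592) or female kidney 3 (0.0686). With technical replicate arrays only, Abcc3 (0.0566) and Dio1 (0.07) did not pass, and Dio1 also did not with no filter (0.0712) or all 8 groups in 1 fit (0.117).

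**Figure D2:**
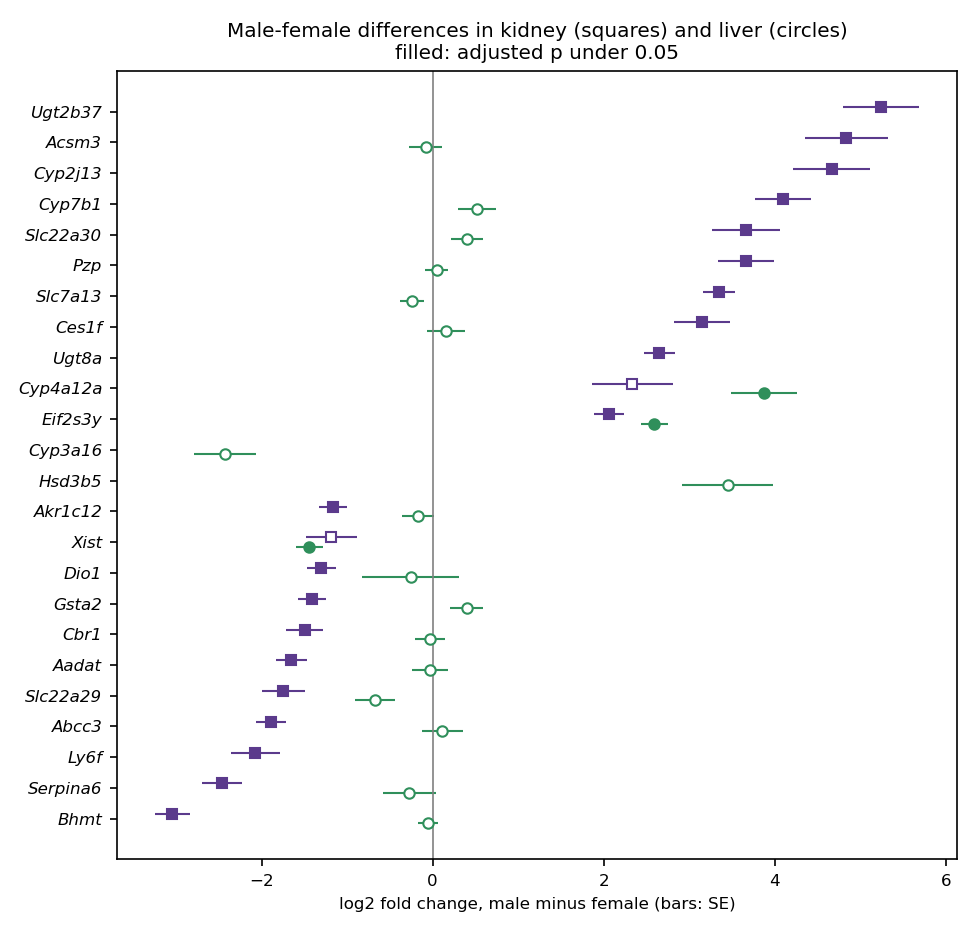
Male minus female log2 difference, with bars of 1 SE, of the genes with the largest differences in kidney (squares) or liver (circles) and of genes whose difference differs between liver and another tissue, with filled symbols for an adjusted p under 0.05. Bhmt lies at -3.04 in kidney and -0.05 in liver, and Ugt2b37 lies at 5.24 in kidney with no liver value, since it was not tested in liver.

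In the hypothalamus, the genes called with a single symbol were Kdm5d, Uty and Xist. Hypothalamic neuropeptides did not pass the test, with 0 of 21 genes called by limma, 0 adjusted over the list alone, 1 at an unadjusted p under 0.05 and an adjusted p of 0.592 by camera. Cartpt, a peptide that lowers food intake, had 1136 ± 149 (SD, n = 3) in male and 1350 ± 97.1 in female hypothalamus, and Hcrt, the wake-promoting peptide orexin, 631 ± 114 and 706 ± 82.6. Receptors for sex steroids and glucocorticoids and steroid enzymes did not pass either (adjusted p = 0.474, 4 measured), nor did oligodendrocyte markers (adjusted p = 0.115) or astrocyte and ependymal markers (adjusted p = 0.251). Muscle markers fell in male hypothalamus (3 genes, adjusted p = 0.000832, adjusted p = 0.229 with an estimated correlation, 0 called by limma, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05), as in Acta1, skeletal actin, at 141 ± 37.0 in male and 578 ± 521 in female hypothalamus. In the hypothalamus 7 of 13771 probe sets passed, 5 higher in male and 2 in female, and 312 had an unadjusted p under 0.05. With the replicate number as a block, 9 passed, 5 higher in male and 4 in female. Leaving out male hypothalamus 1, 2 or 3 left 2 calls each. Kdm5d and Uty were then untested through the filter. With the probe sets of the full comparison kept, 5 of the 7 calls were kept without male hypothalamus 1 and 6 among 7 calls without 2 or 3, against 7 among 8 without female hypothalamus 1, 7 without 2 and 6 without 3.

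Genes called in the same direction in liver and kidney numbered 1, Eif2s3y, against 0.00309 for independent lists. Eif2s3y is Y-linked, so its difference is given by the chromosome wherever it is expressed, and the overlap says nothing on shared regulation. With the replicate number as a block there were 2, Eif2s3y and Cyp4a12a. The male-female difference itself differed between liver and kidney for 40 of 16870 probe sets, between liver and hypothalamus for 3, and between kidney and hypothalamus for 35. With the block these counts were 74, 6 and 64. Acsm3 differed between the sexes by 4.84 in kidney and -0.08 in liver (log2), a difference of -4.92 ± 0.51 (SE, adjusted p = 7.37e-05). Hsd3b5 differed by 3.45 in liver and -0.08 in kidney, a difference of 3.53 ± 0.52 (adjusted p = 0.00253). Its mean log2 value was 5.89 in male and 5.97 in female kidney, near the lowest value that the pseudocount allows. The interaction therefore restates the liver difference, and Hsd3b5 did not pass in liver alone. The joint fit shares 1 spread per probe set over the 6 groups, which for such genes may understate the spread in the expressing group. Cyp4a12a differed by 3.87 in liver and -0.03 in hypothalamus, a difference of 3.91 ± 0.60 (adjusted p = 0.0327). Its mean log2 values in male and female hypothalamus were also low (6.17 and 6.2), where the pseudocount shrinks a sex difference. Without male kidney 1 the 40 probe sets became 25 and without male kidney 2 they became 72. The 35 became 23 without male hypothalamus 1 or 3 or female hypothalamus 2 or 3, 18 without male kidney 3 and 78 without male kidney 2. The 3 became 0 or 1 without any 1 liver or hypothalamus sample other than male liver 2, and 5 without male liver 2, and the call of Cyp4a12a between these tissues was lost in all of these cases but the last (adjusted p from 0.0874 to 0.204). Through the filter, Eif2s3y was untested without any 1 male sample of liver or kidney in that tissue, and with the probe sets of the full comparison kept it stayed shared without any 1 sample.

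Testis and ovary differed in most transcripts. In testis, Tnp2 and Tnp1, transition proteins that replace histones in spermatids, rose to 16007 ± 2119 (SD, n = 3) and 13054 ± 2331 from 4.32 ± 0.71 and 2.35 ± 1.13 in ovary, with a log2 difference of 8.25 ± 0.16 (SE, adjusted p = 5.24e-09) for Tnp2. Ldhc, the lactate dehydrogenase of germ cells, rose by 7.88 ± 0.16, Prm2, a protamine that packs sperm DNA, by 7.38 ± 0.21, and Crisp2, a secretory protein of sperm, by 7.30 ± 0.22. Of 27 measured spermatid genes 26 rose and 1, Crem, fell in testis, with the same numbers adjusted over the list alone and a median log2 difference of 5.64 (camera adjusted p = 6.07e-17, adjusted p = 0.131 with an estimated correlation). All 19 measured spermatocyte genes rose, 19 adjusted over the list alone, with a median of 3.54 (adjusted p = 2.73e-11, adjusted p = 0.131 with an estimated correlation), as in Pgk2, a glycolytic enzyme of meiotic cells, at 6440 ± 2042 in testis and 5.78 ± 2.28 in ovary. Sertoli and Leydig cell genes went both ways, with 4 higher and 8 lower in testis of 15 and adjusted p = 0.956. Rhox5, a homeobox gene of Sertoli cells, rose by 2.77 ± 0.17, and Star, which carries cholesterol into mitochondria for steroid synthesis, fell by 3.41.

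In ovary, Akr1c18, which inactivates progesterone, had 10450 ± 2551 (SD, n = 3) against 68.0 ± 47.7 in testis, a log2 difference of -6.55 ± 0.28 (SE, adjusted p = 1.03e-07). Hsd17b1, an oestradiol-forming enzyme of granulosa cells, differed by -5.11 ± 0.18 on the log2 scale. Ovgp1, a glycoprotein of the oviduct, had 8672.5 ± 1235 against 201 ± 59.7, and Krt19, an epithelial keratin, 1878 ± 417 against 14.1 ± 4.99. Granulosa, theca and luteal cell genes were lower in testis in 19 and higher in 1 of 21 cases, with the same numbers adjusted over the list alone (median -3.27, adjusted p = 3.63e-06, adjusted p = 0.131 with an estimated correlation). Oocyte genes were lower in testis in 13 of 15 cases, 13 adjusted over the list alone (median -1.86, adjusted p = 0.00139, adjusted p = 0.337 with an estimated correlation), as in Zp3, a protein of the egg coat, at 1030 ± 240 in ovary and 97.6 ± 15.9 in testis. All 21 extracellular matrix and smooth muscle genes were lower in testis, 21 adjusted over the list alone (median -2.37, adjusted p = 2.77e-06, adjusted p = 0.182 with an estimated correlation). Adipose markers had a median of -2.90 and did not pass as a list (adjusted p = 0.411), with 4 of 6 lower and 2 higher in testis, as many adjusted over the list alone, among them Fabp4, a fatty acid carrier of adipocytes, at 526 ± 344 in testis and 6482 ± 2029 in ovary.

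**Figure D3:**
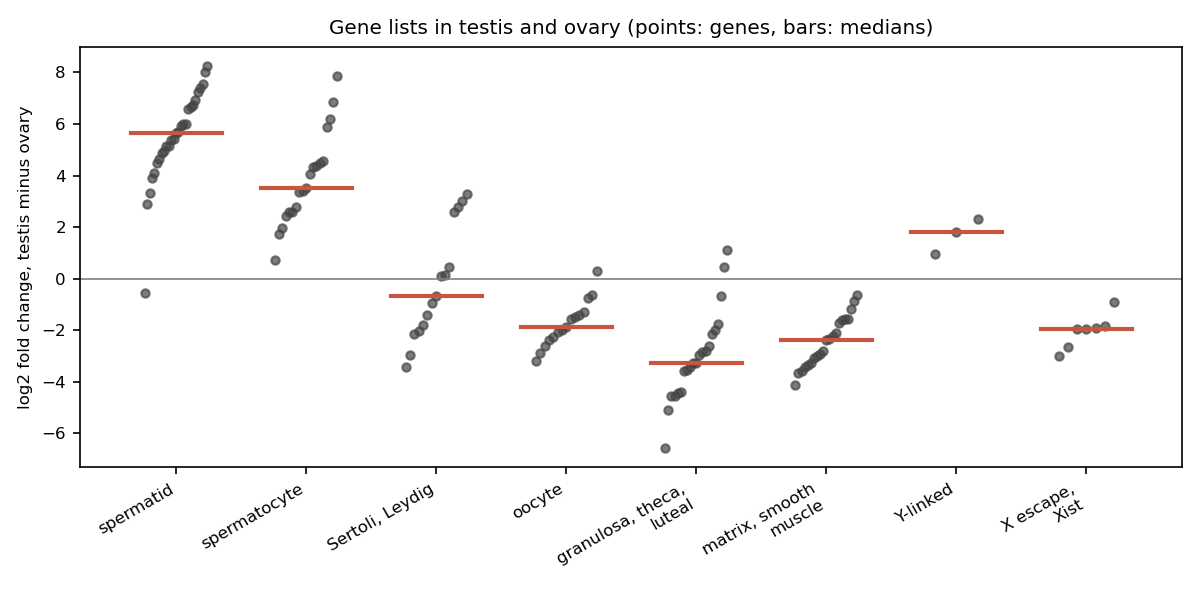
Testis minus ovary log2 difference of each measured gene of 8 lists, with points for genes and red bars for medians. Spermatid genes have a median of 5.64 and granulosa, theca and luteal cell genes one of -3.27.

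Between testis and ovary 10524 of 14928 probe sets passed, 3714 higher in testis and 6810 in ovary. At least 2-fold differences numbered 2415 and 4453. The median log2 difference of all probe sets was -0.35, and it shifted by 0.23 with quantile normalization and 0.37 with median centring. The split of calls became 4687 higher in testis and 5720 in ovary with quantile normalization, and 5225 and 5033 with median centring, so the balance between the groups rests on the scaling.

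Genes on the X chromosome of the reference assembly GRCm38.p6 were lower in testis. Of 279 X-linked genes, 45 (16.1%) were higher in testis, against 2457 (27.7%) of 8874 autosomal genes, an odds ratio of 0.502 (Fisher's exact test, two-sided, 95% interval 0.355 to 0.696, p = 1.11e-05). In ovary 189 X-linked genes (67.7%) were higher, against 3822 (43.1%) of autosomal genes, an odds ratio of 2.78 (2.14 to 3.62, Fisher's exact test, p = 4.67e-16). Genes are not independent replicates, so these p-values describe the array's genes in these samples. All 7 measured members of the list of X-linked genes known to escape inactivation, with Xist added, fell in testis, 7 adjusted over the list alone (camera adjusted p = 0.00708, adjusted p = 0.131 with an estimated correlation), with Eif2s3x, an X-linked translation factor, at 332 ± 13.1 (SD, n = 3) in testis and 2997 ± 446 in ovary. All 3 measured Y-linked genes rose in testis, 3 adjusted over the list alone (adjusted p = 0.0287, adjusted p = 0.182 with an estimated correlation). Tsga8, an X-linked gene of spermatids, rose by 7.49 ± 0.18. Without testis 2 the odds ratio of testis-higher genes was 0.237. Genes expressed in testis alone, such as Tnp2, were then untested through the filter. With the probe sets of the full comparison kept, it lay between 0.461 and 0.536 without any 1 sample.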

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

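All tests on other splits of the samples were set out after the results they measure were seen, while the tests of differences between tissues were planned before.

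Some male-female differences stood out because they passed the test of a difference between tissues, and they number 40 between liver and kidney, 3 between liver and hypothalamus and 35 between kidney and hypothalamus. Between liver and kidney the log2 difference of the sex differences was -4.92 for Acsm3, -4.86 for Ugt2b37, -4.51 for Cyp2j13, -3.62 for Pzp and -3.58 for Slc7a13, whose sex difference lay towards males in kidney. It was 3.53 for Hsd3b5, 2.99 for Bhmt, 2.19 for Serpina6, 2.05 for Ly6f and 2.00 for Abcc3. Between liver and hypothalamus it was -2.50 for Cyp3a16, 3.46 for Hsd3b5 and 3.91 for Cyp4a12a. The mean log2 values in male and female hypothalamus were 5.79 and 5.71 for Cyp3a16 and 5.71 and 5.72 for Hsd3b5. These lie near the lowest value that the pseudocount allows, as do those of Hsd3b5 in kidney (5.89 and 5.97). For these genes the difference between tissues restates that of liver, where neither passed alone. Between kidney and hypothalamus it was -3.13 for Bhmt, -2.10 for Ly6f, -2.06 for Serpina6, -1.81 for Abcc3 and -1.51 for Ugt2b34. In the other direction it was 5.27 for Ugt2b37, 4.87 for Acsm3, 4.86 for Cyp2j13, 4.24 for Slco1a1 and 4.09 for Cyp7b1. In male and female hypothalamus Ugt2b37 (5.72 and 5.75) and Acsm3 (5.95 and 5.99) also lay near that lowest log2 value, so their difference restates that of kidney. Cyp7b1 did not (8.70 and 8.69). Bhmt, Ly6f, Abcc3, Slco1a1 and Cyp4a12a were also dim in hypothalamus, with mean log2 values from 6.17 to 6.58. In male and female liver, Ugt2b37 (6.5 and 6.12) and Cyp2j13 (6.56 and 6.4) were dim. The pseudocount shrinks sex differences at such values, so these differences between tissues largely restate that of the brighter tissue. Ugt2b34 differed by -1.13 in kidney and by 0.38 in hypothalamus, where it was dim (6.38 in males). Slco1a1 and Ugt2b34 did not pass in kidney alone (limma adjusted p = 0.116 and 0.05485). Several of these calls were lost under other settings. Between liver and kidney, Ly6f was lost with 0.25 times the pseudocount (adjusted p = 0.152) and technical replicate arrays only (0.258), Serpina6 with 4 times the pseudocount (0.15) and all 8 groups in 1 fit (0.122), and Abcc3 with first arrays only (0.0607) and technical replicate arrays only (0.0809). Between liver and hypothalamus, Cyp3a16, Hsd3b5 and Cyp4a12a were lost with 4 times the pseudocount (0.127, 0.204 and 0.124), with no filter (0.0659, 0.0659 and 0.0668) and without most single samples. Cyp3a16 and Cyp4a12a were also lost with 0.25 times the pseudocount (0.0589 and 0.0694), Hsd3b5 and Cyp4a12a with technical replicate arrays only (0.11 and 0.0579), and Cyp4a12a with the stricter filter (0.0869) and an intensity trend (0.0794). Between kidney and hypothalamus, Serpina6 was lost with first arrays only (0.552), all 8 groups in 1 fit (0.204), 0.25 and 4 times the pseudocount (0.082 and 0.107) and no filter (0.0523), and Abcc3 with technical replicate arrays only (0.433) and 4 times the pseudocount (0.0545). Slco1a1 was lost there with 4 times the pseudocount (0.168), an intensity trend (0.089), no filter (0.0531) and first arrays only (0.0519). With 0.25 times the pseudocount and technical replicate arrays only, Ugt2b34 (0.202 and 0.136) and Ly6f (0.131 and 0.164) were lost. With the 12 samples of the 2 tissues left out in turn and the same probe sets tested, a setting added after seeing the data, Serpina6 was lost there in 11 cases, Slco1a1 in 10 and Ugt2b34 and Ly6f in 7 each. Between liver and kidney Ly6f was lost in 8 cases and Serpina6 in 3. The labels give total RNA for hypothalamus and polyA-selected RNA for liver and kidney, while another field of them gives total RNA for every sample. Such a difference in RNA was not tested apart from the tissue.

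Of 100 splits of the samples, 11 gave as many probe sets as the 40 between liver and kidney, so chance is not excluded there. The highest of the other splits gave 573, which points to a structure of the samples, and among the 17 splits that part as many numbered pairs 2 gave as many, with 44 as the highest other. For the 3 between liver and hypothalamus, 18 of 100 gave as many, with 15 as the highest other, so chance is not excluded either, and 6 of the 19 that part as many pairs gave as many. For the 35 between kidney and hypothalamus, 4 of 100 gave as many, with 38 as the highest other, but splits that part fewer numbered pairs differ from the real one in that respect. Among the 13 that part as many pairs 1, the real one, gave as many, with 32 as the highest other, and 13 splits are too few for a share under 0.05, so chance is not excluded there. For the 1 gene shared by liver and kidney, 1 of 100 splits, the real one, gave as many, with 0 as the highest other by limma, but the gene is Y-linked, so the split by sex is set apart by the chromosome alone.

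The 10 splits of 3 samples against 3 are too few for a share under 0.05. In liver 2 splits gave at least the real 7 probe sets, and the highest other gave 9, with female liver 1, male liver 1 and male liver 3 on 1 side. Among the 4 liver splits that part all numbered pairs the highest other gave 0 by limma. In kidney 1 split, the real one with 32, gave as many, and the highest other gave 0. In hypothalamus 1 split, the real one with 7, gave as many, and the highest other gave 1. Between testis and ovary 1 split, the real one with 10524, gave as many, and the highest other gave 0.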

How the results depend on the processing

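The block for gene lists, part of the alternatives for the X-linkage odds ratios and leaving out samples with the probe sets kept were chosen after seeing the data, and the other alternatives before. No called gene or list and no odds ratio reversed, but the balance of calls did. The 3714 higher in testis and 6810 in ovary became 5225 and 5033 with median centring. The 5 higher in male and 2 in female hypothalamus became 2 and 3 with the stricter filter, where Kdm5d and Uty were untested. With the filter applied again, 4 and 3 in liver became 0 and 1 without male liver 1 or 3, 5 and 2 in hypothalamus became 0 and 2 without any 1 male sample, and 18 and 14 in kidney became 18 and 19 without male kidney 2. Between liver and hypothalamus, 2 and 1 became 0 and 1 without female liver 1 or 3 with the probe sets kept. Counts in hypothalamus and between testis and ovary and both odds ratios stayed within 1.5 times or on their side of the threshold under every alternative other than leaving out samples. In liver the count was 4 with 4 times the pseudocount, 4 with no filter, 17 with a random block for the RNA sample, 24 with all 8 groups in 1 fit and 11 with the replicate number as a block. In kidney these last 3 gave 88, 131 and 144. Between liver and kidney the count of differing sex differences was 26 with first arrays only, 89 with the random block and 74 with the replicate block. Between liver and hypothalamus it was 1 with 0.25 times the pseudocount, 0 with 4 times the pseudocount, 0 with no filter, 0 with a stricter filter, 1 with technical replicate arrays only, 8 with the random block and 6 with the replicate block. Between kidney and hypothalamus it was 23 with 0.25 times the pseudocount, 23 with first arrays only, 77 with the random block and 64 with the replicate block. The genes shared by liver and kidney were 0 with the stricter filter, 2 with the random block, 3 with all 8 groups in 1 fit and 2 with the replicate block. Leaving out samples in turn, with the filter applied again so that probe sets of 1 group alone were untested without a sample of that group, gave 1 to 3 in liver, 10 to 37 in kidney, 2 to 7 in hypothalamus, 8360 to 10107 between testis and ovary, 25 to 72 between liver and kidney, 0 to 5 between liver and hypothalamus, 18 to 78 between kidney and hypothalamus and 0 to 1 for shared genes. The odds ratios lay at 0.237 to 0.555 in testis and 2.72 to 3.39 in ovary. With the probe sets kept these were 4 to 7, 15 to 53, 5 to 8, 9583 to 11292, 28 to 74, 0 to 6, 21 to 80, 1 throughout, 0.461 to 0.536 and 2.59 to 2.79. The cause was not tested, though a left-out sample leaves fewer samples and no filter more probe sets. With an estimated correlation, 23 gene list results lost their call and 51 kept their side of the threshold. Signal over background limits dim genes, whose differences the pseudocount shrinks.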

Other observations

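All tests of the 3 patterns weighed here were chosen after the results were seen, and members whose values had been seen were left out of the lists of genes induced by interferon-gamma and of transcripts with detained introns.

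In kidney, organic anion and cation transporters moved both ways. Slc22a30 rose in male kidney, and Abcc3 and Slc22a29, a relative of Slc22a30 on a shared probe design, fell, by 1.89 and 1.75 on the log2 scale. The call of Slc22a29 was lost with 0.25 times the pseudocount (adjusted p = 0.0652), no filter (0.144), first arrays only (0.0994) and without any 1 kidney sample other than male kidney 2 (0.157 to 0.251). Slco1a1, an uptake carrier, had 1988 ± 1847 (SD, n = 3) in male and 30.5 ± 4.85 in female kidney (limma adjusted p = 0.116, and 0.0228 with the replicate number as a block), and Slc22a6, the organic anion exchanger of the proximal tubule, 5276 ± 1568 and 2240 ± 37.1 (adjusted p = 0.174, and 0.0316 with the block). Of 27 transporters 1 rose and 2 fell, and adjusted over the list alone 5 rose and 6 fell (camera adjusted p = 0.459). With the block 5 rose and 5 fell over all genes. Between testis and ovary, 5 of 25 heat shock and unfolded protein response genes rose in testis and 15 fell (adjusted p = 0.183, and 0.0194 under quantile normalization), with 5 and 15 adjusted over the list alone. Dnajb1, a co-chaperone, had 9067 ± 1218 in testis and 1056 ± 163 in ovary, and Hspa1b, an inducible chaperone, 162 ± 55.6 and 2842.5 ± 325. Proliferation genes had 11 higher and 6 lower in testis of 22, as many adjusted over the list alone (adjusted p = 0.121), as in Ccnb2, a cyclin of mitosis and meiosis, at 3516 ± 342 and 534 ± 136.

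Dbp and Arntl, 2 clock genes chosen after their values were seen, differed between samples of 1 group. Per3, another, had 113.4, 426 and 173.4 in female liver 1, 2 and 3 but 164.6, 182.6 and 171.8 in male liver 1, 2 and 3. Dbp, an output gene of the clock, had 167.8, 2100 and 150 in female liver 1, 2 and 3 and 315.3, 735.1 and 166 in male liver 1, 2 and 3. Arntl, a core activator of the clock, had 601.7, 112.2 and 645.2 in female liver and 492.3, 288.8 and 523.2 in male liver.

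MHC class II genes, which present antigen, were lower in sample 1 of both sexes in liver and kidney, with Cd74 at 2641 in male liver 1 against 15180 and 16140 in male liver 2 and 3, and a median log2 range within groups of 2.11 over 4 genes. Array scaling is argued against, since 15358 probe sets had a median range of 0.387. The 22 other immune cell markers had one of 0.886, at most 1.73, against at least 2.06 for the 4 genes. These 4 were set apart from the immune list after their values were seen. The gap therefore does not decide on a smaller share of immune cells. Some immune cells did vary along, since the macrophage markers Csf1r and Adgre1 were lowest in sample 1 of both sexes in both tissues, with Adgre1 at 902.5, 2019 and 1684 in male liver 1, 2 and 3. A candidate explanation is an interferon-gamma response in samples 2 and 3, since 9 of 12 other genes induced by interferon-gamma differed by sample number, against 471 of 9338 other genes (odds ratio 56.4, Fisher's exact test, two-sided, p = 4.41e-10, genes not independent). The test by sample number has no direction, so it does not show that these genes were higher in samples 2 and 3. A smaller share of immune cells and a change in a single class of antigen-presenting cells stay open, and the labels do not say what the numbers stand for. By sample number 849 of 15358 probe sets differed in the 12 samples of liver and kidney (4058 at an unadjusted p under 0.05). In the 12 samples of hypothalamus and gonads 0 of 16582 did by limma (994 at an unadjusted p under 0.05), and in the 6 samples of hypothalamus alone 7 of 13771 did (2135 at an unadjusted p under 0.05).

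Xist had 804.7, 416.2 and 311.9 in female kidney 1, 2 and 3. Male RNA in female kidney 3 is argued against, since Eif2s3y reached 1.26% of the male mean there, where the shortfall of Xist would need 61.2%. Kdm5d and Uty had 38.15 and 38.75 there and 9.35 and 27 in female kidney 1. With male means of 162.3 and 197.2, they also stayed under that share. Degraded RNA is argued against too, since the 3' to 5' ratio of Gapdh was 1.03 times and that of actin 0.955 times that of female kidney 1. A lower share of nuclear RNA may account for the lower Xist, since 16 transcripts with introns detained in the nucleus had a median log2 difference of -0.468 between female kidney 3 and 1 (all genes 0.03), 15 of them lower, at the 0.01 percentile of 10000 random lists of like expression. This sets 1 sample against 1, so the percentile measures a spread over genes, which are not independent, and none between samples. In male kidney of the same numbers the median was -0.687, with 14 of 16 lower, and Malat1, a nuclear RNA, had 1205 and 178.1 in male kidney 1 and 3 and 857 and 173 in female kidney 1 and 3. Whether this lies in the tissue or in the RNA preparation stays open, and no biological explanation was tested.

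Exocrine pancreas transcripts were present in liver, with Ctrb1, a digestive protease, at 2156 to 11730 in the 6 liver samples against 34.45 to 385.5 in the samples of the other tissues, lowest in male liver 2 and highest in male liver 3. Probes that read a liver transcript of steady level are argued against, since the 10 markers had a median log2 range of 2.4 over the liver samples, against 0.509 for all probe sets. Such a range does not decide on a liver transcript that itself varies between samples. Pancreas tissue in the liver samples is a candidate explanation, since 1 factor per sample accounted for 94.8% of the variance of the markers about their means. Of the 14 genes on the list 10 were measured, and some digestive enzymes are also made outside the pancreas. No biological explanation was tested.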
